A study of Rattus norvegicus with 224 samples.

How the data were processed

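Total RNA of rat aortic smooth muscle cells was amplified with Cyanine-5 and hybridised to Agilent rat arrays beside Cyanine-3 reference RNA from pools of newborn rat pups, per the labels and the series' design text. The authors deposited 1 table of scores for 224 arrays and 11575 features, with 0 missing values. The design text says that the authors scanned with GenePix software, normalized by loess, filtered features under an intensity of 30 or with under 70% good data, and imputed missing values from 3 nearest neighbours. It adds that principal components linked to the 4 replicate runs were removed and that the data were standardized. The deposited scores bear this out in part: each array had mean 0 and SD 1, feature means over arrays lay between -0.207 and 0.217, and 4 singular values were near 0. The indicator of each run lay for 73.1% to 89.3% in those missing dimensions. Run means that differ between hours were left in part: component 4 held 43.8% of its variance between sets of run and hour, with 3.26% between runs and 0.101% between hours. Array extremes ran from -27.8 to 26.7, and 223 arrays carried 3 decimals and 1 carried 9. Background, flags and scanner intensities were not used here.

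The scale is standardized, so a difference is a number of array SDs. The log base and the gene-wise scaling before deposition are not given in the sources used here. The comparisons had been planned for log2 ratios, and the same linear model was kept for the scores. The ratio's direction is likely cells over reference, from the dyes in the labels and the software's convention. The pairwise correlations reached -0.53 at the lowest, and 1.46% of array pairs lay under -0.3. Centring each feature over the arrays makes negative correlations arise between arrays of different kinds, so they do not settle the direction, and with the sign turned every higher below would read lower with sizes and counts unchanged. For the same reason the level of genes abundant in the pup reference could not check the direction. The sample labels and the design text differ on the dish size, the serum level and the length of quiescence, and this was left open.

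Probe names came from the platform annotation: 7473 probes had 1 gene symbol, 2 had several and 4100 had none here, which gave 6502 genes. Entrez identifiers of 7461 probes were found in the RefSeq gene table, and 0 symbols changed. Where a gene had several probes (854 genes), the first in the table stood for it, and 1 gene, Rsu1, had probes called in opposite directions, in the comparison of the drugs at 24 h.

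Scores were fitted with limma 3.58.1 in R 4.3.3, with 56 group means and the run as a block on all 224 arrays, which share 1 estimate of the spread (165 residual degrees of freedom, median residual SD 0.811). The run is stated in the labels and the design text as a replicate run, which is where the pairing comes from. Deviations from group means correlated at 0.0210 on average within a run, at 0.0654 within a run and hour, and at -0.0218 within a run across hours. Moderated statistics came from eBayes, and a probe was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each of 29 designed comparisons. Drug contrasts averaged the 4 combinations of insulin and glucose. Insulin and glucose were tested in DMSO cells, and their averages over all 7 drug conditions were set as a second way of testing them. The comparisons, alternatives, gene lists and the rule for named genes were fixed before the data were examined. That rule takes the 10 named probes with the largest rise and the 10 with the largest fall among those called with the same sign in all 4 runs, for lower doses and interactions 3 and 3, for a described list the 3 and 3 called members that changed most, and Cdkn1a, Txnip, Tagln, Tubb5 and Pcna whatever their result.

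A set of 28 gene lists was tested with camera (preset correlation 0.01) over genes, with adjustment over 252 tests for the designed comparisons and 252 for those with the averages. Of 62 lists called among the designed comparisons, 11 held with a correlation estimated from the residuals, and of 37 called for the averages 12 held. The preset test treats genes as nearly independent and takes the array as the unit, so the run medians are given where runs differ. Markers of other cell types that explanted cultures could hold made up 4 lists. Over the 9 main comparisons their smallest adjusted p was 0.105 for endothelial cells, 0.393 for leukocytes, 0.109 for adventitial fibroblasts and 0.126 for cartilage and bone cells. Genes abundant in pup tissues formed another list, with a smallest adjusted p of 0.00315.

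The procedure was tested on simulated data with 200 of 11575 probes shifted by 1 or 2 array SDs. For 16 against 16 arrays (100 ng/mL rapamycin at 6 h) it called 42% of shifts of 1 and 97% of shifts of 2. For 8 against 8 (insulin in DMSO cells at 6 h) these were 17% and 76%, for 56 against 56 (the insulin average at 6 h) 93% and 100%, and for the interaction of rapamycin with time 24% and 76%. These simulations held no effect of run and hour. For comparisons against the same DMSO arrays, unchanged groups were drawn 100 times with the residual SD of each probe. The overlap of their calls, and that with the 2 comparisons taken from different runs, were added after the overlaps were seen. With the 4 runs as the unit and the observed spread between runs, 8% and 69% were called for 100 ng/mL rapamycin at 6 h, 9% and 70% at 24 h, 55% and 96% for the insulin average at 6 h, 67% and 94% at 24 h, 78% and 98% for the glucose average at 6 h, and 51% and 91% at 24 h. Shifts of single probes under 1 were not simulated. The probes called from all arrays had median sizes of 0.598 and 0.602 for the insulin averages at 6 and 24 h. For the glucose averages these were 0.696 and 0.596. The share called at such sizes is thus not known. For 100 ng/mL rapamycin at 6 h, a mitosis list shifted by 0.5 was called (adjusted p = 5.38e-09) with 0 other lists.

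Alternatives were no block, the compared groups alone, quantile normalization, array medians set to 0, array weights, a trend with a robust prior, probes of a gene averaged, and runs or doubtful arrays left out. Lists were also tested with fry. Added after seeing the data were run by hour as a block, a random run-by-hour block for time (statmod 1.5.0), the near-identical arrays left out, and the 4 runs as the unit, in which limma was fitted to 1 difference per run. The last was added because the calls of the insulin average at 24 h were seen to depend on single runs, with 40 left without run A and 6 without run C. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.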

Results

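Smooth muscle cells explanted from the aortas of newborn rats were profiled on 224 Agilent 2-colour arrays. Quiescent cells were held in 5 or 25 mM glucose for 24 h before stimulation, per the design text. They received 100 nM insulin or its vehicle, then DMSO, rapamycin at 0.01, 1 or 100 ng/mL, or paclitaxel at 0.01, 1 or 1000 ng/mL, for 6 or 24 h. Rapamycin inhibits the mTOR kinase and paclitaxel stabilises microtubules, and both drugs are coated on coronary stents. The 56 groups each held 4 arrays, 1 from each of the replicate runs A to D, so every dose of a drug had 16 arrays per hour over the 4 combinations of insulin and glucose. The deposited values were standardized scores with mean 0 and SD 1 in each array, so differences below are in array SDs and not log2 folds. Array medians lay between -0.099 and 0.094. The features were near centred, so a score above 0 lies above the gene's own average over the 224 arrays and does not compare the cells with the pooled pup reference. Higher likely means more RNA than in the other arm, since the labels put the cells in Cyanine-5 and the scanner software by convention divides that dye by Cyanine-3. If the ratio had been taken the other way, all directions would turn together. The number of arrays limited the precision, with a median SE of 0.286 for 16 against 16 arrays, 0.405 for 8 against 8 and 0.153 for 56 against 56. In run A, the insulin and vehicle arrays of 0.01 ng/mL rapamycin at 6 h and 25 mM glucose were nearly identical (r = 0.99993, with 99.5% of scores within 0.01), so that arm held 15 distinct arrays. The labels do not say whether the runs came from separate animals or cultures, and p-values measured the spread between these arrays.

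The first question was what rapamycin changed in these cells. At 100 ng/mL for 6 h, Tsc22d3, a glucocorticoid- and FOXO-induced leucine zipper gene, rose most among named genes, from a mean score of -1.14 ± 1.30 (SD, n = 16) in DMSO to 3.56 ± 1.11 (SD, n = 16). The difference was 4.70 ± 0.428 (SE, adjusted p = 8.56e-18). Cd55, a complement regulator, rose by 3.71 ± 0.614, and the gap junction gene Gjb2 by 3.17 ± 0.802. Cspg4, Kcnn4, Anxa8, Inhbb and Mthfs rose by 2.07 to 2.75. Among falling genes were the replication helicase gene Mcm5 (-2.69 ± 0.512, adjusted p = 0.000117), the glucose transporter gene Slc2a1 (-2.46 ± 0.481) and Ddit4, a stress-induced mTOR regulator (-2.28 ± 0.473). Ankrd1, Jag1, Snrpa, Bnip3, Ppa1, Pls3 and Mcm6 fell by between 1.84 and 2.13, with values of -2.13 for Ankrd1 and -1.84 for Mcm6. In all, 588 probes were called by limma at an adjusted p under 0.05, 336 higher and 252 lower. With the 4 runs as the unit, 163 were called, 147 of them among the 588, and without run A 212 were called.

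Several fixed gene lists moved with 100 ng/mL rapamycin at 6 h. Of 21 immediate early genes, 5 rose (5 adjusted over the list alone), led by the Krüppel-like factors Klf6 (2.50 ± 0.332), Klf4 (2.25 ± 0.359) and Klf10 (1.80 ± 0.288), and the list rose as a whole (camera adjusted p = 2.40e-06). Of 27 DNA replication genes, 6 fell (13 adjusted over the list alone), among them Cdt1 (-1.82 ± 0.353). That list fell at adjusted p = 4.71e-08, but adjusted p = 0.215 with an estimated correlation. Heat shock genes fell in 7 of 18 members (8 adjusted over the list alone, with 1 higher), including Hspe1 (-1.60 ± 0.369), Hsph1 (-1.32 ± 0.347) and Ahsa1 (-1.24 ± 0.248). The list had an adjusted p = 0.000276. Proteasome subunits fell in 4 of 27 members (8 adjusted over the list alone), led by Psmb6 (-1.13 ± 0.231), with adjusted p = 3.64e-06. Glycolysis and HIF-1 target genes fell in 4 of 22 members (5 adjusted over the list alone), Slc2a1, Bnip3, Pdk1 and Pfkl. The list had an adjusted p = 0.00372 and adjusted p = 0.499 with an estimated correlation. Ribosome biogenesis genes fell in 3 of 19 members while Nob1 rose (7 lower and 2 higher adjusted over the list alone), at adjusted p = 0.00552 and adjusted p = 0.412 with an estimated correlation. The respiratory chain list was lower (2 of 40 fell, 6 adjusted over the list alone; adjusted p = 0.00171, and adjusted p = 0.299 with an estimated correlation). The p53 targets were lower (Ddit4 alone of 16, and 1 adjusted over the list alone; adjusted p = 0.0243, and adjusted p = 0.265 with an estimated correlation). The lysosome and autophagy list passed as higher (adjusted p = 0.0164, and adjusted p = 0.287 with an estimated correlation). Its single called member of 24, over all genes and over the list alone, was however the autophagy receptor gene Sqstm1, which fell by 1.02 ± 0.249. Of the genes named whatever their result, Pcna fell by 0.895 ± 0.276 (adjusted p = 0.0351). Cdkn1a (-0.778 ± 0.30), Txnip (0.593 ± 0.602), Tagln (0.0833 ± 0.527) and Tubb5 (0.0749 ± 0.413) did not pass.

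At 24 h, 100 ng/mL rapamycin lowered Thbd, which encodes the anticoagulant receptor thrombomodulin, from 2.20 ± 1.64 (SD, n = 16) to -2.61 ± 1.18 (SD, n = 16). The difference was -4.81 ± 0.477 (SE, adjusted p = 5.40e-15). Genes of dividing cells fell with it, among them Mki67 (-3.36 ± 0.630), Pimreg (-3.32 ± 0.595), Pclaf (-3.24 ± 0.589), Cdk1 (-3.20 ± 0.593) and Cks2 (-3.04 ± 0.522). Of 28 mitosis genes, 7 fell (17 adjusted over the list alone; camera adjusted p = 1.14e-13, and adjusted p = 0.184 with an estimated correlation). Of 27 DNA replication genes 7 fell (13 adjusted over the list alone; adjusted p = 5.28e-10, and adjusted p = 0.143 with an estimated correlation). Mcm5 stood at -2.69 ± 0.512 and Uhrf1 at -2.17 ± 0.500. The median difference of the mitosis list was below 0 in each run, from -1.24 to -0.88. Rising genes were Cd55 (2.77 ± 0.614), Anxa8 (2.66 ± 0.512), the elastic fibre gene Mfap5 (2.17 ± 0.402), the growth factor gene Igf1 (2.17 ± 0.519), Sts (2.02 ± 0.335) and Rnasek, Prss23, Pcsk6, Ppp1r37 and Pim3 (1.59 to 1.96). Tnfrsf11b, Ifi27l2b and Ska1 fell by -2.65, -2.58 and -2.54.

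Smaller list changes at 24 h of 100 ng/mL rapamycin were each lost with an estimated correlation. Endoplasmic reticulum chaperone genes fell in 2 of 16 members, Calr (-1.26 ± 0.367) and Sel1l (-1.09 ± 0.205) (8 adjusted over the list alone; adjusted p = 2.40e-05, and adjusted p = 0.204 with an estimated correlation). ATF4 target and amino acid genes fell in 2 of 24, Phgdh and Slc1a5 (2 adjusted over the list alone; adjusted p = 0.000581, and adjusted p = 0.536 with an estimated correlation), with run medians from -1.89 in D to 0.19 in C. The p53 targets Ddit4 and Phlda3 fell out of 16 (6 adjusted over the list alone; adjusted p = 0.000661, and adjusted p = 0.0743 with an estimated correlation). The NRF2 targets Osgin1 (-2.02 ± 0.482) and Gstp1 (-1.55 ± 0.381) fell out of 21 (5 adjusted over the list alone; adjusted p = 0.0202, and adjusted p = 0.141 with an estimated correlation). Atp5mc1, Ndufs8 and Cox8a fell out of 40 respiratory chain genes (4 adjusted over the list alone; adjusted p = 0.00372, and adjusted p = 0.331 with an estimated correlation). Sterol synthesis and ribosomal protein lists passed as higher (adjusted p = 0.0100 and 0.00852, and adjusted p = 0.626 and 0.412 with an estimated correlation) with 0 members called by limma over all genes or over either list alone. Cdkn1a (-0.337 ± 0.30), Txnip (-0.221 ± 0.602), Tagln (0.290 ± 0.527), Tubb5 (-0.113 ± 0.413) and Pcna (-0.672 ± 0.276) did not pass. A total of 261 probes were called, 99 higher and 162 lower. With the runs as the unit 59 were called, 47 of them shared, and without run C 97 were called.

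The dose series asked how far these changes depended on the rapamycin concentration. At 1 ng/mL for 6 h, Tsc22d3 rose by 2.60 ± 0.428 (n = 16 and 16, adjusted p = 1.83e-05), Mthfs by 2.13 ± 0.508 and Bcas3 by 1.62 ± 0.361, while Ddit4 (-2.53 ± 0.473), Slc2a1 (-2.17 ± 0.481) and Bnip3 (-1.99 ± 0.512) fell. At 24 h, Lmo7, Prss23 and Tmem250 rose by 1.92, 1.69 and 1.41, and Thbd (-3.03 ± 0.477, adjusted p = 1.85e-05), the nuclear receptor gene Nr4a1 (-3.03 ± 0.637) and Cks2 (-2.83 ± 0.522) fell. Spreads were uneven for some of these. Mthfs at 6 h had an SD of 3.61 in DMSO and 1.08 at 1 ng/mL, and Nr4a1 at 24 h had 1.40 and 3.17. The contrasts of 1 ng/mL with DMSO called 178 probes at 6 h (95 higher, 83 lower) and 170 at 24 h (30 higher, 140 lower). With the runs as the unit limma called 9 and 0, with 1064 at an unadjusted p under 0.05 at 24 h. Without run A 53 were called at 6 h, and without run D 44 at 24 h. When the compared groups alone were fitted, 102 were called at 24 h, while run by hour as a block called more than 170.

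At 0.01 ng/mL, limma called 0 probes at either hour, with 397 and 203 at an unadjusted p under 0.05. The higher dose exceeded 1 ng/mL for Cd55 (2.79 ± 0.614, adjusted p = 0.0237), Tsc22d3 (2.10 ± 0.428) and the GTPase gene Rhob (1.98 ± 0.412) at 6 h, and Sox4 was lower (-1.47 ± 0.315). That direct contrast called 6 probes at 6 h and 4 at 24 h, where none of the 4 had a gene symbol. It called 1 probe at 6 h without run C or with the compared groups alone, and 4 with the runs as the unit. At 24 h it called 1 without run B and, by limma, 0 with the runs as the unit, with 774 at an unadjusted p under 0.05. The effects of 100 and 1 ng/mL correlated across probes at r = 0.744 at 6 h and 0.651 at 24 h, where unchanged groups sharing the DMSO arrays gave 0.500 and 0.498. Their covariances were 0.144 and 0.131, against 0.0561 and 0.0557 in that simulation. Called at both doses were 81 higher and 70 lower probes at 6 h and 10 and 66 at 24 h. Unchanged groups sharing the DMSO arrays, with lists of the real length, shared 25.8 and 19.6 at 6 h (at most 36 and 29) and 5.14 and 21.6 at 24 h (at most 11 and 30). The 10 higher at 24 h thus lay above the mean of these draws but not above their highest. These lists held unchanged probes alone, so they do not give the overlap of lists that hold real effects. Lists without shared arrays or effects would share 2.76 and 1.81, and 0.257 and 1.96. Taking the doses from different runs gave r = 0.327 and 0.236, and on average 3.83 higher and 2.33 lower in common at 6 h and 0.167 and 3.83 at 24 h, from far fewer calls. Probes are not independent replicates.

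**Figure D1:**
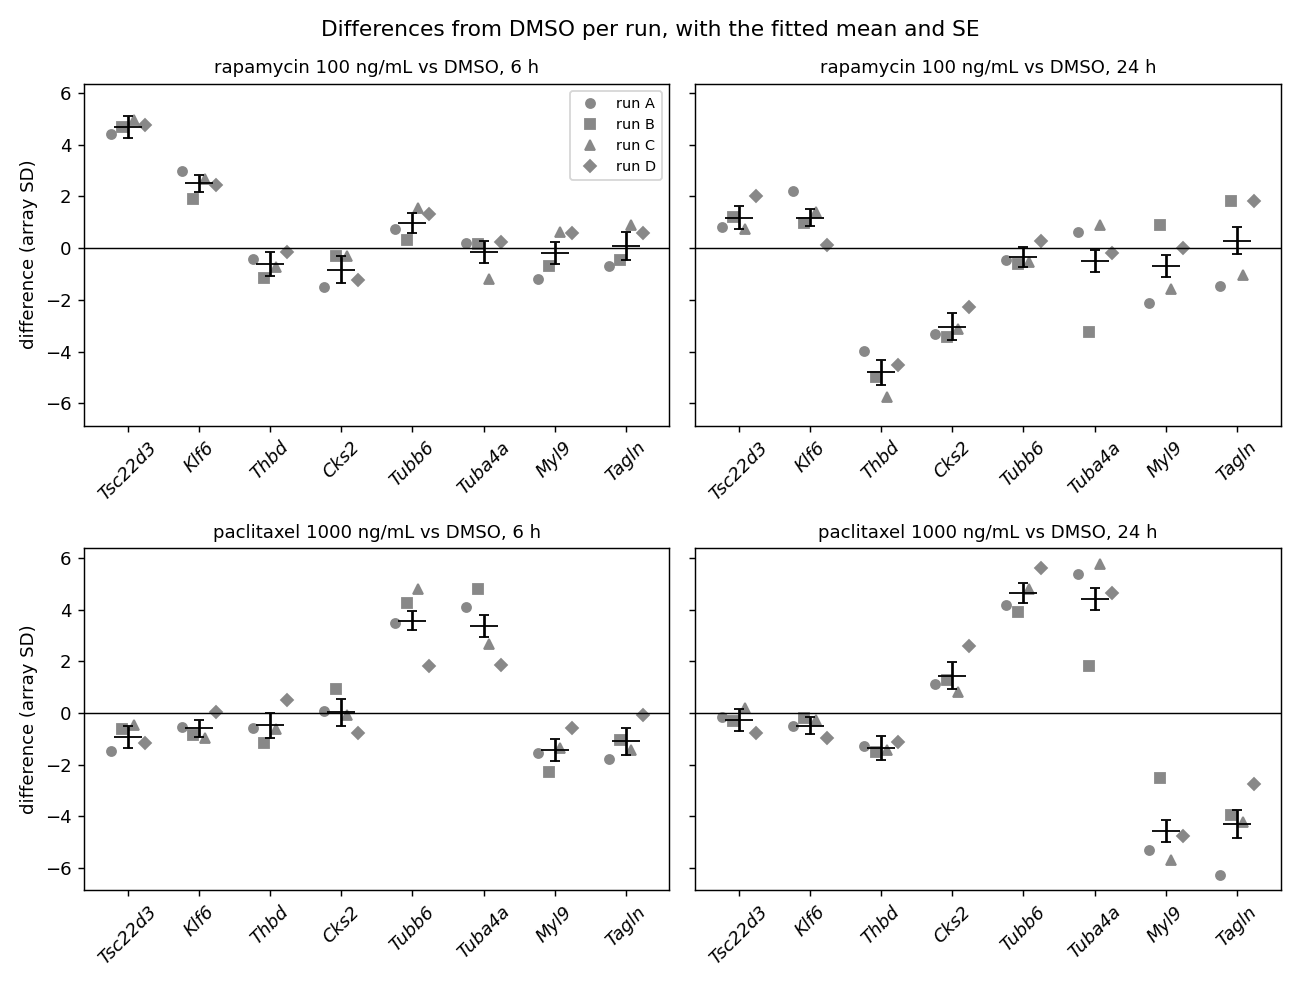
Differences from DMSO cells in array SDs (vertical axis) for 8 genes named by the fixed rule, under 100 ng/mL rapamycin and 1000 ng/mL paclitaxel at 6 and 24 h, with 1 grey point per run and the fitted mean ± SE as a black bar. Tsc22d3 under rapamycin at 6 h lies between 4.40 and 4.96 in the 4 runs, and Tubb6 under paclitaxel at 24 h between 3.90 and 5.62.

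Paclitaxel was compared with DMSO in the same way. At 1000 ng/mL for 6 h, tubulin genes rose: Tubb6 from -0.418 ± 1.05 (SD, n = 16) to 3.16 ± 1.42 (SD, n = 16), a difference of 3.57 ± 0.383 (SE, adjusted p = 6.43e-13). Also higher were Tuba4a by 3.35 ± 0.425, Tuba1a by 2.53 ± 0.509, Tuba8 by 2.02 ± 0.468 and Tubb5 by 1.83 ± 0.413. These were 5 of the 15 tubulin and microtubule genes (6 adjusted over the list alone, with Tubg1; camera adjusted p = 6.51e-12). Rangrf, Pck2, Aldh1l2, Scly and the kinase gene Eif2ak3 rose by 1.23 to 1.74. Of 21 immediate early genes, Ccn1 (-2.85 ± 0.516, adjusted p = 0.000367), Ccn2 (-1.60 ± 0.390) and Zfp36 (-1.53 ± 0.345) fell (5 adjusted over the list alone; list adjusted p = 3.64e-06). Trim47, Ywhah, Pkd1 and Pdcl3 also fell, with values of -1.52, -1.05, -0.880 and -0.872. The contractile list fell as a whole (adjusted p = 6.72e-08) with none of 21 members called over all genes. Adjusted over the list alone 6 were lower, Myl9 at -1.44 ± 0.428 and Vcl at -1.19 ± 0.319 among them.

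The ATF4 target list was higher after 6 h of paclitaxel (adjusted p = 2.40e-06, and adjusted p = 0.352 with an estimated correlation). Limma called 0 of 24 members over all genes and 2 when adjusted over the list alone, Trib3 at 2.67 ± 0.763 and Chac1 at 2.64 ± 0.754. Sterol synthesis genes were lower (adjusted p = 2.40e-06, and adjusted p = 0.301 with an estimated correlation; 0 of 16 called, and Fdps and Sc5d adjusted over the list alone). So was the respiratory chain list (adjusted p = 0.0425, and adjusted p = 0.53 with an estimated correlation; 0 of 40 called either way). Cdkn1a (0.237 ± 0.30), Txnip (0.604 ± 0.602), Tagln (-1.09 ± 0.527) and Pcna (-0.187 ± 0.276) did not pass. Of the 34 probes called, 19 were higher and 15 lower. With the runs as the unit Ccn1 was the 1 call, and 9 were called without run A, while 61 were called with run by hour as a block.

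At 24 h the tubulin differences under 1000 ng/mL paclitaxel were 4.85 ± 0.509 for Tuba1a, 4.62 ± 0.383 for Tubb6 (adjusted p = 1.39e-20), 4.40 ± 0.425 for Tuba4a, 3.35 ± 0.413 for Tubb5 and 2.90 ± 0.468 for Tuba8. The list rose in 5 of 15 members over all genes and over the list alone (adjusted p = 6.51e-12), although its median difference was 0.152. Contractile smooth muscle genes fell in 7 of 21 members (11 adjusted over the list alone; adjusted p = 5.72e-17). The myosin light chain gene Myl9 went from -0.532 ± 1.98 to -5.11 ± 2.14 (SD, n = 16 and 16), a difference of -4.58 ± 0.428 (SE, adjusted p = 5.35e-17). Tagln fell by 4.30 ± 0.527 and the vinculin gene Vcl by 1.92 ± 0.319. Other falling genes were Il1rl1 (-3.52 ± 1.01), Ccn1 (-2.62 ± 0.516), the tissue factor gene F3 (-2.57 ± 0.536), Ankrd1 (-2.49 ± 0.519) and Ddah1, Prss23, Glipr1 and Mcm5 (-2.41 to -2.29). Rangrf, Gtse1 and Ppp1r37 rose by 3.18, 2.21 and 2.19.

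Mitosis genes rose after 24 h of paclitaxel in 2 of 28 members, Cenpf (3.00 ± 0.808) and Kif23 (2.15 ± 0.606) (8 adjusted over the list alone; adjusted p = 2.08e-06, and adjusted p = 0.412 with an estimated correlation). The p53 targets Cdkn1a, a cyclin-dependent kinase inhibitor gene (1.41 ± 0.30, adjusted p = 0.00136), and Tp53inp1 rose out of 16 (4 adjusted over the list alone; list adjusted p = 0.00552, and adjusted p = 0.183 with an estimated correlation). Lower lists were DNA replication (Mcm5 of 27, with 2 adjusted over the list alone; adjusted p = 0.0243, and adjusted p = 0.636 with an estimated correlation) and sterol synthesis (0 of 16 either way; adjusted p = 0.0111, and adjusted p = 0.626 with an estimated correlation). Immediate early genes were lower (Ccn1 of 21, with 2 adjusted over the list alone; adjusted p = 0.0158, and adjusted p = 0.183 with an estimated correlation). The lysosome list was higher (0 of 24 called, 2 adjusted over the list alone; adjusted p = 0.0164, and adjusted p = 0.287 with an estimated correlation). Beside these, genes abundant in newborn pup tissues, which fill the reference channel, were lower (adjusted p = 0.00315, and adjusted p = 0.265 with an estimated correlation; 0 of 33 called either way). The extracellular matrix list did not pass in any of the tested comparisons. Its smallest adjusted p = 0.139 was in this contrast, where 1 of 31 members rose (3 higher and 2 lower adjusted over the list alone). Txnip (-0.0149 ± 0.602) and Pcna (-0.362 ± 0.276) did not pass. In total 153 probes were called, 56 higher and 97 lower, with 46 called with the runs as the unit (33 shared) and 35 without run D.

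Paclitaxel at 1 and 0.01 ng/mL gave 0 calls by limma at either hour, with 599 and 215 probes at an unadjusted p under 0.05 for 1 ng/mL, and 349 and 203 for 0.01 ng/mL. Against 1 ng/mL directly, 1000 ng/mL raised Trib3 (3.48 ± 0.763, n = 16 and 16, adjusted p = 0.0101), Chac1 (3.33 ± 0.754) and Tubb6 (2.77 ± 0.383) at 6 h and lowered Ccn1 (-2.28 ± 0.516). At 24 h Tuba4a, Tuba1a and Tubb6 were higher by 4.67, 4.53 and 4.53, and Tagln (-4.85 ± 0.527), Myl9 (-4.81 ± 0.428) and Ankrd1 (-2.85 ± 0.519) were lower. These contrasts called 17 and 146 probes. Without run D they called 5 and 65, with run by hour as a block 34 and 220, and with the runs as the unit 13 and 71, while the compared groups alone gave 38 at 6 h.

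The drugs were also compared with each other at their highest doses, which differed (100 and 1000 ng/mL). At 6 h, Tsc22d3 (5.63 ± 0.428, n = 16 and 16, adjusted p = 5.64e-24), Cd55 (5.40 ± 0.614) and Gjb2 (4.35 ± 0.802) were higher under rapamycin, and Tuba4a (-3.49 ± 0.425), Ddit4 (-2.82 ± 0.473) and Trib3 (-2.59 ± 0.763) were lower. At 24 h, Cd55, Tagln and Gjb2 were higher by 4.60, 4.59 and 4.55, and Pimreg (-5.38 ± 0.595), the kinetochore gene Cenpf (-5.26 ± 0.808) and Tuba1a (-5.18 ± 0.509) were lower. The contrast called 778 probes at 6 h and 766 at 24 h. With the runs as the unit 265 and 360 were called, and 380 at 6 h without run A and 392 at 24 h without run D. Against DMSO, probes called for both drugs numbered 0 higher, 2 lower and 2 opposite at 6 h, and 2 higher, 5 lower and 6 opposite at 24 h. Unchanged groups sharing the DMSO arrays, with lists of the real length, shared 6.77 higher and 5.1 lower at 6 h and 7.71 and 16.8 at 24 h, more than the real ones. Their lists held unchanged probes alone, which limits this comparison. Lists without shared arrays or effects would share 0.552 and 0.327, and 0.479 and 1.36. The effects of the drugs correlated at r = 0.268 and 0.210, below the 0.499 of unchanged groups sharing the DMSO arrays at both hours, and their covariances of 0.0469 and 0.0422 stood against 0.0559 in the simulation. With the drugs taken from different runs, r was -0.0187 and -0.0197. Real but unrelated effects of the drugs would also bring r below that of unchanged groups, so the lower r does not show opposed effects.

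Insulin was compared with vehicle first in DMSO cells (n = 8 and 8 arrays per hour). Limma called 0 probes at 6 h and 0 at 24 h, with 661 and 410 at an unadjusted p under 0.05. The glycolysis list was higher at 6 h (adjusted p = 7.12e-07, and adjusted p = 0.218 with an estimated correlation), with Slc16a3 at 2.31 ± 0.806 and Pdk1 at 1.92 ± 0.559 among 6 of 22 members higher when adjusted over the list alone. NRF2 targets were higher at 6 h (adjusted p = 1.98e-05), with Gstp1 at 1.86 ± 0.539 as the 1 member of 21 adjusted over the list alone. At 24 h the sterol synthesis list was higher (adjusted p = 1.21e-06, and adjusted p = 0.287 with an estimated correlation; Tm7sf2 at 2.57 ± 0.714 as the 1 of 16 adjusted over the list alone). Proteasome genes were higher and mitosis genes lower at 6 h (adjusted p = 0.00281 and 3.99e-05, and adjusted p = 0.183 and 0.505 with an estimated correlation), with 0 members called either way. Lists of DNA replication (Lig1 adjusted over the list alone; adjusted p = 2.40e-06), respiratory chain (Cox8a adjusted over the list alone; adjusted p = 0.000105), mitosis (adjusted p = 0.00171) and contractile genes (adjusted p = 0.00188) were higher at 24 h and lysosome genes lower (adjusted p = 0.0407). With an estimated correlation these became adjusted p = 0.286, 0.215, 0.636, 0.133 and 0.356. Of the genes named throughout, the differences at 6 and 24 h were 0.248 and 0.845 for Cdkn1a, -0.0712 and -1.51 for Txnip, 0.0658 and 1.16 for Tagln, 1.12 and 0.690 for Tubb5, and 0.148 and 0.443 for Pcna, none past the threshold.

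Averaged over DMSO and the 6 drug conditions (n = 56 and 56), insulin at 6 h went with higher Slc16a3, a lactate transporter gene (2.57 ± 0.305, adjusted p = 3.39e-11), Higd1a (2.19 ± 0.305), Tmem106a (2.01 ± 0.253), Slc2a1 (2.00 ± 0.257), Bnip3 (1.93 ± 0.273) and Pdk1 (1.73 ± 0.211). It went with lower Fam180a (-2.01 ± 0.302), Ypel3 (-1.91 ± 0.190, adjusted p = 6.74e-15), Cdo1 (-1.82 ± 0.275) and the glutamine synthetase gene Glul (-1.47 ± 0.166). Of 22 glycolysis and HIF-1 target genes, 16 were higher and Adm lower, over all genes and over the list alone (camera adjusted p = 1.49e-21). The median of this list was above 0 in each run, at 1.24, 0.49, 1.24 and 0.38 in A to D. Mitosis genes were lower in 5 of 28 members, Cenpf and Kif23 among them (9 adjusted over the list alone; adjusted p = 7.95e-06, and adjusted p = 0.420 with an estimated correlation). Chaperone genes of the endoplasmic reticulum were higher in 5 of 16 (9 adjusted over the list alone; adjusted p = 2.28e-05, and adjusted p = 0.120 with an estimated correlation). Proteasome genes (6 of 27, 11 adjusted over the list alone; adjusted p = 0.000103), NRF2 targets (Nqo1, Hmox1 and 3 more of 21, 7 adjusted over the list alone; adjusted p = 0.00300) and heat shock genes (4 of 18, 5 and 1 lower adjusted over the list alone; adjusted p = 0.0236, and adjusted p = 0.222 with an estimated correlation) were higher. Immediate early genes (Ccn1, Zfp36 and Nr4a2 of 21 either way; adjusted p = 0.000277) and ribosomal protein genes (0 of 45 either way; adjusted p = 0.0134, and adjusted p = 0.420 with an estimated correlation) were lower. The sterol list passed (adjusted p = 0.0401, and adjusted p = 0.635 with an estimated correlation; Acat2 of 16, with 2 adjusted over the list alone), but its run medians were 1.45, -0.08, 0.59 and -0.44. Genes repressed by insulin through FOXO did not pass (adjusted p = 0.123; 3 of 18 lower and 1 higher, over all genes and over the list alone). Beside these, adventitial fibroblast markers were lower (adjusted p = 0.0251, and adjusted p = 0.0700 with an estimated correlation), with Thy1 at -0.420 ± 0.128 as the 1 called of 9 and 2 adjusted over the list alone. The array-level fit called 818 probes, 415 higher and 403 lower. When probes were called from 3 runs, 71.8% of the calls had the same sign in the run left out. The fit called 164 without run A and 175 without run C, but 1094 without run B. Each arm held 1 of the near-identical arrays of run A, and without both 834 were called, 800 of them shared. With the 4 runs as the unit limma called 0, with 1611 at an unadjusted p under 0.05, and the differences of separate runs correlated at r = 0.0291 to 0.558.

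At 24 h the insulin average went with higher Adh1c (1.96 ± 0.346, n = 56 and 56, adjusted p = 3.13e-05), Lpar1 (1.61 ± 0.244), Igfbp4 (1.60 ± 0.265) and Nxn (1.37 ± 0.180) and lower Lmcd1 (-2.47 ± 0.63) and Gstp1 (-1.16 ± 0.204). Sterol synthesis genes were higher in 3 of 16 members, Tm7sf2, Idi1 and Sqle (11 adjusted over the list alone; adjusted p = 1.08e-06, and adjusted p = 0.230 with an estimated correlation), with run medians of 1.03, 0.12, 0.48 and 0.35. Mitosis genes were higher in 2 of 28 (3 adjusted over the list alone; adjusted p = 9.79e-05, and adjusted p = 0.498 with an estimated correlation), with a median of 0.98 in run C and at most 0.27 in the others. Cdkn1a was higher by 0.610 ± 0.160 (adjusted p = 0.0116), in 3 of 4 runs. Of 461 probes called, 297 were higher and 164 lower. Without run A 40 were called and without run C 6, but 667 without run B and 682 without run D. The share with the same sign in the run left out was 59.0%. Limma called 0 with the runs as the unit, with 1108 at an unadjusted p under 0.05.

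Glucose at 25 mM was compared with 5 mM first in DMSO cells (n = 8 and 8). At 6 h, 4 probes were called: Cfc1 was higher (2.59 ± 0.576, adjusted p = 0.0399, but 1.40 and adjusted p = 0.764 without run A, where 1 array had -11.8), the collagen prolyl hydroxylase gene P4ha2 (-2.24 ± 0.500) and Map7 (-1.81 ± 0.395) were lower, and the other had no gene symbol. At 24 h, 33 were called, 25 higher and 8 lower. The potassium channel gene Kcnk2 (2.84 ± 0.626, adjusted p = 0.0135), Cyp1b1 (2.68 ± 0.565) and the glutaredoxin gene Glrx (2.33 ± 0.483) were higher, and Ppp1r15a, a stress-induced phosphatase subunit gene (-2.84 ± 0.728), the chaperone gene Hsp90b1 (-2.50 ± 0.638) and Map2k1 (-1.88 ± 0.47) were lower. Lurap1l, Vkorc1, Cbr3, Sec23a, Gpx8, Tnfrsf1a and Tm7sf3 were higher by 1.38 to 1.97. At 6 h the lists of DNA replication (0 of 27 called, 10 lower adjusted over the list alone; adjusted p = 1.45e-10), mitosis (0 of 28, 4 adjusted over the list alone; adjusted p = 2.46e-10), glycolysis (P4ha2 of 22 either way; adjusted p = 2.40e-06) and tubulin genes (0 of 15 either way; adjusted p = 0.0409) were lower. Those of sterol synthesis (0 of 16, Lss adjusted over the list alone; adjusted p = 0.000657), lysosome (adjusted p = 0.000983) and fatty acid synthesis genes (adjusted p = 0.0114) were higher. None of these held with an estimated correlation, where the smallest was adjusted p = 0.132. At 24 h the ATF4 list was lower (Lars1 of 24, 12 adjusted over the list alone; adjusted p = 2.46e-10, and adjusted p = 0.215 with an estimated correlation), with run medians of 0.45, -3.95, 0.24 and -2.36. Chaperone genes were lower (Hsp90b1 of 16, 9 adjusted over the list alone; adjusted p = 1.06e-08). Ribosome biogenesis and glycolysis lists were lower and proteasome and respiratory chain lists higher at 24 h (adjusted p = 0.000248, 0.0371, 0.0113 and 0.0302, and adjusted p = 0.287, 0.636, 0.261 and 0.499 with an estimated correlation). Both counts depended on the setting. The compared groups alone gave 0 and 0, without run A 0 were called at 6 h, and without run B 0 at 24 h. At 24 h array weights gave 91 and run by hour as a block 96, and the runs as the unit gave 1 at 6 h and, by limma, 0 at 24 h, with 991 at an unadjusted p under 0.05. Differences at 6 and 24 h were 0.0244 and 0.926 for Cdkn1a, 0.581 and -0.944 for Txnip, 0.0495 and -0.426 for Tagln, -0.817 and -0.265 for Tubb5, and -0.942 and 0.628 for Pcna, none past the threshold.

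Averaged over the 7 drug conditions (n = 56 and 56), 25 mM glucose at 6 h lowered genes of dividing cells. Cenpf fell by 2.18 ± 0.432, the proliferation marker gene Mki67 from 1.5 ± 1.67 to -0.611 ± 1.60 (SD), a difference of -2.11 ± 0.337 (SE, adjusted p = 2.52e-06), Pclaf by 1.93 ± 0.315 and Cdk1 by 1.72 ± 0.317. Of 28 mitosis genes 15 fell (23 adjusted over the list alone; adjusted p = 2.32e-24), and of 27 DNA replication genes 10 fell (16 adjusted over the list alone; adjusted p = 7.46e-16). Both lists had medians below 0 in each run, from -1.31 to -0.45 and from -0.72 to -0.32. Spp1, the osteopontin gene (1.92 ± 0.272), Rgs3 (1.49 ± 0.233), Fabp5 (1.38 ± 0.367) and the mevalonate pathway gene Mvd (1.37 ± 0.251) rose. Sterol synthesis genes rose in 6 of 16 members (12 adjusted over the list alone; adjusted p = 6.39e-12, and adjusted p = 0.0700 with an estimated correlation). Fatty acid synthesis genes rose in 3 of 13, Scd2, Fasn and Fads1 (6 adjusted over the list alone; adjusted p = 8.44e-05, and adjusted p = 0.0580 with an estimated correlation). Glycolysis genes fell in 7 of 22, including Pgk1 (-1.13 ± 0.265), Bnip3 and Pdk1 (14 adjusted over the list alone; adjusted p = 6.58e-10, and adjusted p = 0.0630 with an estimated correlation). The lysosome list was higher with Neu1 called of 24, over all genes and over the list alone (adjusted p = 0.000265, and adjusted p = 0.0624 with an estimated correlation). The pentose phosphate list did not pass (adjusted p = 0.0569; 1 of 4 higher either way). Tubulin genes (Stmn1 of 15, 2 adjusted over the list alone; adjusted p = 0.00276) and ribosomal protein genes (Rpl39 of 45, 0 adjusted over the list alone; adjusted p = 0.0148) were lower and ATF4 targets higher (0 of 24 either way; adjusted p = 0.0135). With an estimated correlation these became adjusted p = 0.0700, 0.438 and 0.628. Pcna fell by 0.651 ± 0.148. Of the 409 probes called, 182 were higher and 227 lower, and 206 were called with the runs as the unit, 176 of them shared. Without run A 227 were called and without run D 226. The 25 mM arm held both near-identical arrays of run A, and without them 386 were called, 358 of them shared.

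At 24 h the glucose average called 1159 probes, 631 higher and 528 lower, and 573 without run D and 643 without run B. The share with the same sign in the run left out was 74.5%. With the runs as the unit limma called 0, with 1591 at an unadjusted p under 0.05. Serpina3n (2.20 ± 0.424), Pgm5 (1.92 ± 0.291), Spp1 (1.85 ± 0.272) and Glrx (1.54 ± 0.183, n = 56 and 56, adjusted p = 5.90e-11) were higher, and Plk2 (-2.26 ± 0.256, adjusted p = 6.68e-12), Ppp1r15a (-2.10 ± 0.275) and Hsp90b1 (-1.77 ± 0.241) lower. ATF4 target genes were lower in 19 of 24 members (20 adjusted over the list alone; adjusted p = 2.32e-24), with Trib3 at -2.83 ± 0.408, Slc7a5 at -2.47 ± 0.381 and Chac1 at -2.47 ± 0.403. This lay in runs B and D, where the list medians were -2.83 and -1.95, against 0.31 in A and 0.30 in C. Chaperone genes of the endoplasmic reticulum were lower in 11 of 16 (13 adjusted over the list alone; adjusted p = 2.93e-14), with medians of -0.17, -1.32, -0.18 and -1.23 in A to D. Ribosome biogenesis genes were lower in 11 of 19, led by Rcl1 (-1.38 ± 0.240) (12 adjusted over the list alone; adjusted p = 1.93e-10), with medians of -0.18, -0.88, -0.21 and -0.75. The NRF2 target Nqo1 was higher by 1.94 ± 0.284, with 4 of 21 members of its list higher and 1 lower (5 and 2 adjusted over the list alone; adjusted p = 0.0150, and adjusted p = 0.0700 with an estimated correlation). Ribosomal protein genes were lower (8 of 45, 10 adjusted over the list alone; adjusted p = 3.80e-05, and adjusted p = 0.126 with an estimated correlation). Higher were proteasome (3 of 27, 6 adjusted over the list alone; adjusted p = 0.000175) and lysosome genes (4 of 24, 6 adjusted over the list alone; adjusted p = 0.0148, and adjusted p = 0.234 with an estimated correlation). Sterol synthesis (3 of 16, 4 adjusted over the list alone) and glycolysis genes (3 of 22 with Hk1 higher, 4 and 1 adjusted over the list alone) were lower at adjusted p = 0.0366 and 0.0444, and adjusted p = 0.634 and 0.617 with an estimated correlation. Cdkn1a was higher at 24 h by 0.482 ± 0.160 (adjusted p = 0.0348), in all 4 runs. Tagln (0.204), Tubb5 (-0.166) and Pcna (0.0139) did not pass at 24 h. Txnip, known as a glucose-induced gene, differed by 0.324 ± 0.322 at 6 h and 0.222 ± 0.322 at 24 h and did not pass.

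**Figure D2:**
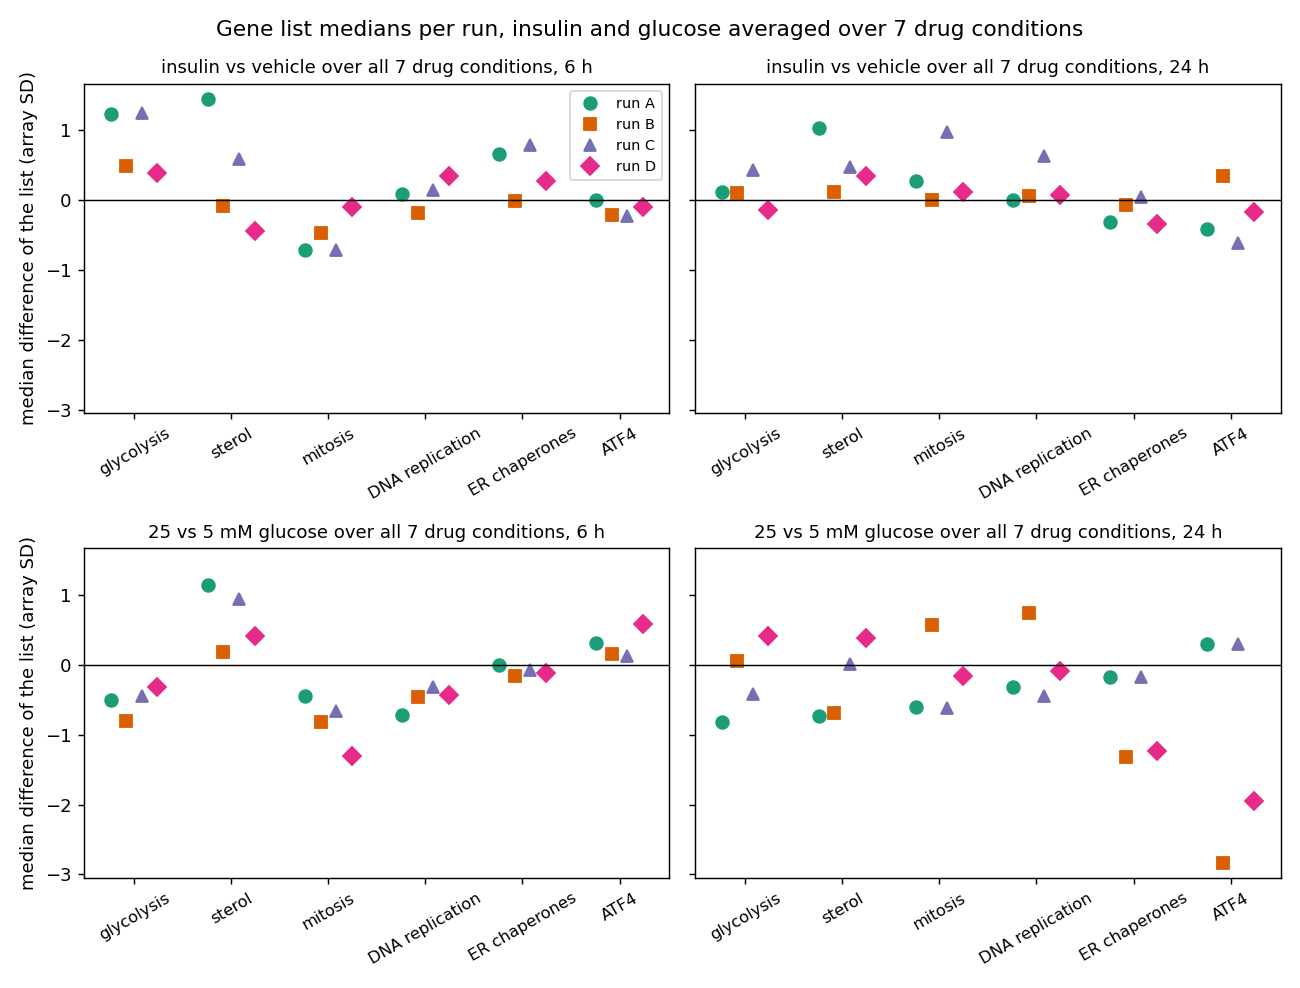
Median difference of 6 gene lists in array SDs (vertical axis) per replicate run, for insulin against vehicle and 25 against 5 mM glucose, averaged over 7 drug conditions at 6 and 24 h, with 1 point per run. In the glucose comparison at 24 h the ATF4 list lies at -2.83 and -1.95 in runs B and D and at 0.31 and 0.30 in A and C. In that at 6 h the mitosis list lies between -1.31 and -0.45.

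Culture time was compared in DMSO cells, 24 h against 6 h (n = 16 and 16). The gap junction gene Gja5 was higher by 4.30 ± 0.602 (adjusted p = 4.02e-08), Ifi27l2b by 4.27 ± 0.777, the inflammatory caspase gene Casp4 by 4.16 ± 0.906 and Thbd by 2.69 ± 0.477. Nqo1 (-3.12 ± 0.531), Lurap1l (-2.87 ± 0.357), Nrp1 (-2.73 ± 0.410) and Myl9 (-2.20 ± 0.428) were lower, as were Cdkn1a (-1.69 ± 0.30) and Tubb5 (-1.5 ± 0.413). Tagln (-1.47 ± 0.527), Pcna (-0.553 ± 0.276) and Txnip (-0.177 ± 0.602) did not pass. Contractile genes were lower in 5 of 21 members (7 adjusted over the list alone; adjusted p = 7.90e-05). C3 and Nfkb1 were higher out of 25 cytokine and NF-kB genes, over all genes and over the list alone (adjusted p = 0.0456, and adjusted p = 0.301 with an estimated correlation). ATF4 targets were higher in 5 of 24 (9 adjusted over the list alone; adjusted p = 3.09e-07, and adjusted p = 0.301 with an estimated correlation), with run medians of -0.01, 2.25, -0.06 and 1.39. Chaperone genes were higher in 3 of 16 with Ssr1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.000198, and adjusted p = 0.261 with an estimated correlation). DNA replication genes (2 of 27, 3 adjusted over the list alone) and ribosomal protein genes (4 of 45 either way) were lower at adjusted p = 0.00281 and 0.00423, and adjusted p = 0.516 and 0.359 with an estimated correlation. The fit called 838 probes, 499 higher and 339 lower, against 354 without run C, 490 without run A and 509 without run D. With the runs as the unit 5 were called, Lurap1l and Nrp1 among them.

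Interaction terms asked whether a drug effect at the highest dose depended on insulin, glucose or time (n = 32 arrays per drug arm and 32 DMSO arrays). Limma called 0 probes for rapamycin by insulin, rapamycin by glucose, paclitaxel by insulin and paclitaxel by glucose, with 509, 510, 357 and 399 at an unadjusted p under 0.05. The rapamycin effect differed between hours for 11 probes, with Thbd at -4.19 ± 0.674 (adjusted p = 4.42e-05), Pimreg at -3.62 ± 0.841 and Tsc22d3 at -3.51 ± 0.606 for the 24 h effect minus the 6 h effect. For paclitaxel by time, Myl9 was the only probe called (-3.13 ± 0.605, adjusted p = 0.00724). This does not show a lack of difference elsewhere, as Tagln had -1.09 at 6 h and -4.30 at 24 h and was not called. The counts of 11 and 1 became 7 and 0 with the runs as the unit, by limma with 931 and 597 at an unadjusted p under 0.05, and 3 and 0 without run A. Without run B they became 26 and 4.

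**Figure D3:**
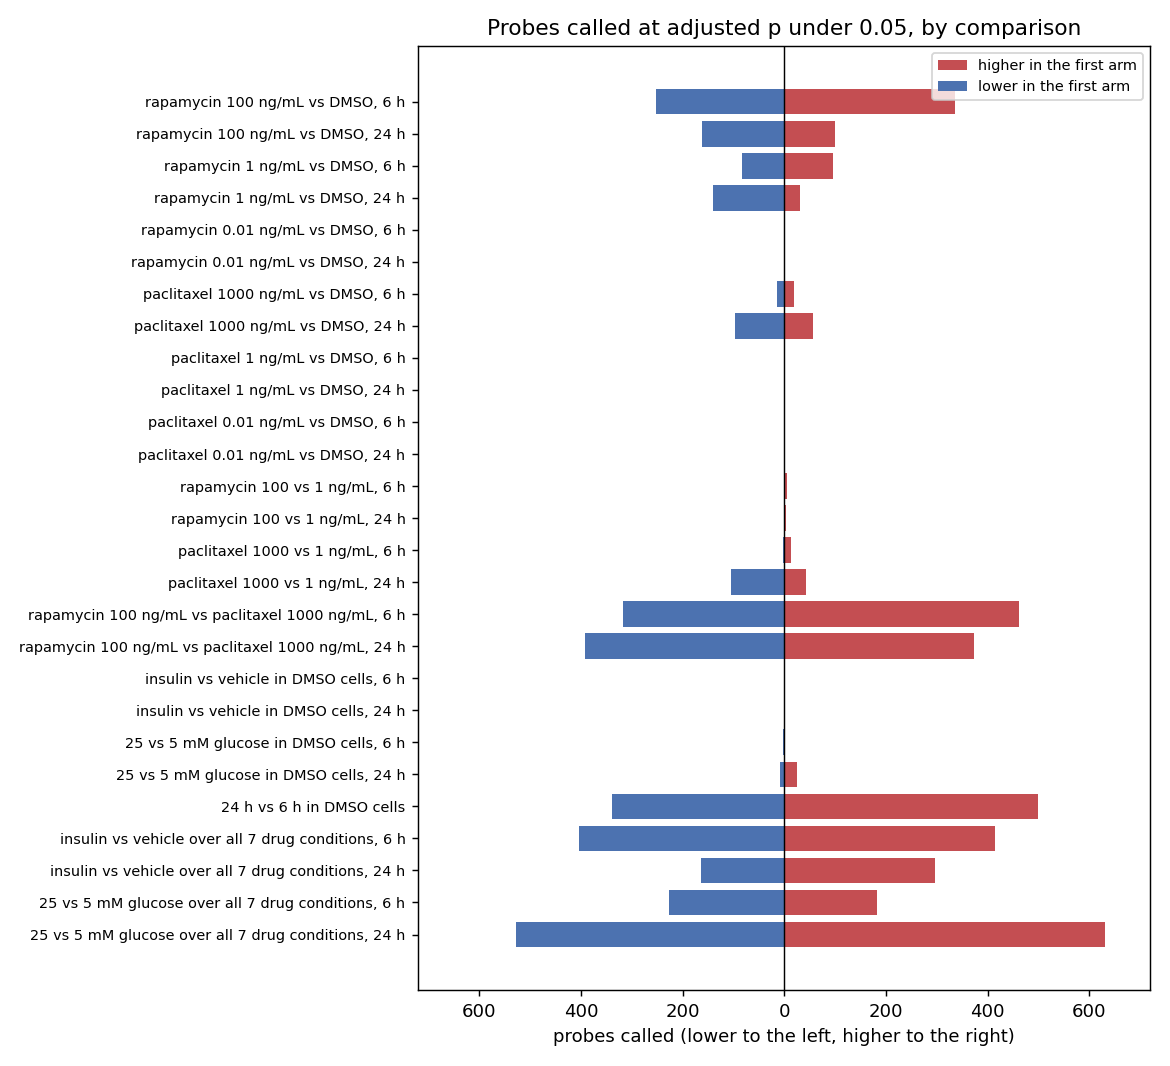
Number of probes called at an adjusted p under 0.05 (horizontal axis, lower to the left in blue and higher to the right in red) for each comparison other than the interactions, by the array-level fit. The bars for 0.01 ng/mL of either drug are empty, and those for 100 ng/mL rapamycin at 6 h reach 336 higher and 252 lower.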

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

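The tests of the near-identical arrays were chosen after the result was seen. The rule for single arrays looked, in 72 arms of 8 arrays of the named genes, for a score whose gap to the next was large against the range of its arm, and found 6. The ratios below are that gap over the range. For Cfc1, the DMSO vehicle array of run A at 6 h and 5 mM glucose had -11.8 where the next was -1.99 (ratio 0.779), and without that run the difference fell from 2.59 to 1.40 (adjusted p = 0.764), so the call for Cfc1 depended on that run. Map2k1 had 4.82 in the DMSO vehicle array of run D at 24 h and 5 mM (next 1.02, ratio 0.795), and without that run its difference was -1.55 (adjusted p = 0.279). Vkorc1 had 2.16 in the DMSO vehicle array of run A at that hour and glucose (next -0.509, ratio 0.612). Txnip had -2.72 in the DMSO insulin array of run A at 24 h and 5 mM (next -0.292, ratio 0.607). Tagln had -2.21 in the DMSO vehicle array of run D at 6 h and 5 mM, against a next of 0.933 in the insulin comparison and 0.486 in the glucose comparison (ratios 0.660 and 0.566). No array was dropped for this. Arms of 16 or more arrays, which the drug comparisons used, were not searched for single arrays. There Mthfs and Trim47 in DMSO at 6 h had SDs of 3.61 and 2.51. These stood against 1.31 under 100 ng/mL rapamycin and 0.814 under 1000 ng/mL paclitaxel. Both differences had the same sign in all 4 runs.

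The rapamycin effect differed between hours for 11 probes. Thbd (-4.19), Pimreg (-3.62), Gprc5a (-2.61), Serpine2 (-2.29), Msrb2 (-1.61) and Cd82 (-1.22) had a lower difference at 24 h, as did Tsc22d3 (-3.51), which rose by 4.70 at 6 h and had 1.19 at 24 h. The 4 probes without a gene symbol had -3.88, -1.94, -1.30 and 2.70. Under paclitaxel, Myl9 had -3.13.

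In run A, 2 arrays of different insulin treatment had near-identical scores, with an SD of the difference of 0.0118 where the smallest of all other pairs was 0.769. The same groups in the other runs correlated at 0.0513 at most, which speaks against equal expression as the cause. One hybridization deposited under both titles is likely, and the files do not tell which title is right.

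Insulin gave 0 calls in DMSO cells and 818 over all 7 conditions at 6 h. The insulin differences in DMSO cells had a slope of 0.842 on those of the other conditions, whose own slopes ran from 0.619 to 0.925. The difference between insulin and vehicle arrays was thus not confined to drug-treated cells. Both sides of the slope came from the same 4 runs, so a difference particular to single runs would raise it too. The slope cannot tell such a difference from an effect of insulin. With the same 8 against 8 arrays, the other 6 conditions called 0, 1, 1, 0, 1 and 9 probes at 6 h and at most 1 at 24 h, so few calls were not particular to DMSO cells. Fewer arrays could thus be the cause, but at 24 h the slope of 0.600 lay below the others (0.719 to 0.957), which leaves it open at that hour. With the 4 runs as the unit, limma called 0 for the average at 6 h too, with 1611 at an unadjusted p under 0.05, and 71.8% of calls from 3 runs had the same sign in the run left out.

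The effects of 1 and 100 ng/mL rapamycin were alike. Taken from different runs, so that no DMSO array was shared, they still correlated at 0.327 at 6 h, so shared arrays were not the whole cause. A response at its ceiling by 1 ng/mL could give this and would need a covariance ratio near 1. The ratio was 0.745 at 6 h (0.581 to 0.848 over splits of the runs) and 0.671 at 24 h (0.439 to 0.783), so no split at either hour reached the 0.9 set for a ceiling. Both ratios lay under the 0.75 set against it, but their ranges did not, and that the ranges should do so was required only after they were seen. The values thus speak against a full ceiling without excluding it over all probes. At 6 h the direct contrast of the doses called 6 probes, Tsc22d3 among them (2.10 ± 0.428). With the 4 runs as the unit it called 4, and without run C 1. For the probes called, this argues against a ceiling by 1 ng/mL.

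Arrays were also regrouped 100 times without regard to run or matched sets, the real grouping included, and the regroupings with as many calls as the real one were counted. That count was 1 for 100 ng/mL rapamycin at both hours (most calls in another grouping 55 and 6), for 1 ng/mL rapamycin (5 and 5), for 1000 ng/mL paclitaxel (12 and 99), for rapamycin against paclitaxel (19 and 119), for time (54), for the insulin averages (86 and 63) and for the glucose averages (1 and 4). For 100 against 1 ng/mL rapamycin it was 1 and 2 (2 and 4), for 1000 against 1 ng/mL paclitaxel 1 and 2 (3 and 226), and for glucose in DMSO cells 2 and 1 (6 and 11). Where 0 probes were called it was 100 by construction, so it tests nothing there: rapamycin at 0.01 ng/mL (175 and 299), paclitaxel at 1 ng/mL (16 and 11) and 0.01 ng/mL (83 and 93), and insulin in DMSO cells (3 and 48). For 0.01 ng/mL rapamycin, 0.01 ng/mL paclitaxel and 1000 against 1 ng/mL paclitaxel at 24 h, some regroupings called many more probes than the real one. These regroupings mix arrays of different insulin, glucose and run, and which of these they followed was not tested.

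Swapping arms within pairs of the same run and condition keeps the block. The pairs of a run were swapped separately, so a difference that they share is broken up and the swaps do not test whether runs agree. The insulin averages and the glucose average at 24 h, for which limma called 0 with the runs as the unit, are cases of this. The count was then 1 for 100 ng/mL rapamycin (most calls in another grouping 50 and 11), 1 ng/mL rapamycin (14 and 18), 1000 ng/mL paclitaxel (6 and 122), 100 against 1 ng/mL rapamycin (1 and 1), 1000 against 1 ng/mL paclitaxel (1 and 44), rapamycin against paclitaxel (96 and 165), time (84), the insulin averages (5 and 16) and the glucose averages (1 and 43). For glucose in DMSO cells it was 1 at 6 h (2) and 3 at 24 h, where another grouping called 131 against the real 33. Again by construction, it was 100 for rapamycin at 0.01 ng/mL (1 and 0), paclitaxel at 1 ng/mL (1 and 1) and 0.01 ng/mL (0 and 1), and insulin in DMSO cells (2 and 1). For interactions, swaps within matched sets gave 1 for rapamycin by time (1) and paclitaxel by time (0). They gave 100, by construction, for rapamycin by insulin (0), rapamycin by glucose (2), paclitaxel by insulin (0) and paclitaxel by glucose (0).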

How the results depend on the processing

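Alternatives fixed beforehand were no block, leaving out 1 run, the compared groups alone, quantile normalization, array medians at 0, array weights, a trend with a robust prior, averaged probes, leaving out 2 arrays marked as repeats or 1 with a short glucose label, and averages over the drug conditions. Run by hour as a block, a random run-by-hour block, leaving out the 2 near-identical arrays and the 4 runs as the unit were chosen after the results were seen. Filters for missing values and imputation could not be varied, as 0 values were missing, and removal of run components was void, as 0 of the first 10 components lay over 50% between runs. Why counts moved was not tested.

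With 1 run left out, the counts ran from 212 to 482 (6 h) and 97 to 193 (24 h) for 100 ng/mL rapamycin, 53 to 162 and 44 to 166 for 1 ng/mL rapamycin, 9 to 22 and 35 to 177 for 1000 ng/mL paclitaxel, 1 to 3 and 1 to 4 for 100 against 1 ng/mL rapamycin, 5 to 14 and 65 to 125 for 1000 against 1 ng/mL paclitaxel, and 380 to 668 and 392 to 593 for rapamycin against paclitaxel. They ran from 0 to 3 and 0 to 83 for glucose in DMSO cells, 354 to 918 for time, 3 to 26 for rapamycin by time, 0 to 4 for paclitaxel by time, 164 to 1094 and 6 to 682 for the insulin averages, and 226 to 319 and 573 to 1145 for the glucose averages.

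With the 4 runs as the unit, counts were 163 and 59 for 100 ng/mL rapamycin, 9 and 0 for 1 ng/mL, 1 and 46 for 1000 ng/mL paclitaxel, 0 for 100 against 1 ng/mL rapamycin at 24 h, 71 for 1000 against 1 ng/mL paclitaxel at 24 h, and 265 and 360 for rapamycin against paclitaxel. Glucose in DMSO cells gave 1 and 0, time 5, rapamycin by time 7, paclitaxel by time 0, the insulin averages 0 and 0, and the glucose averages 206 and 0. Of 566 gene results, which include named genes not called in the main fit, 386 lost their call. The share of calls from 3 runs with the same sign in the run left out was 92.7% and 88.2% for 100 ng/mL rapamycin, 71.8% and 59.0% for the insulin averages, and 91.3% and 74.5% for the glucose averages.

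Without the block, so with the pairing by run dropped, paclitaxel by time called 0 probes, 100 ng/mL rapamycin 531 and 242, 1 ng/mL rapamycin 150 and 150, 1000 ng/mL paclitaxel 32 and 133, glucose in DMSO cells at 24 h 28 and time 768. Apart from paclitaxel by time, all counts stayed within a factor of 1.5. With run by hour as a block, 262 were called for 1 ng/mL rapamycin at 24 h, 61 for 1000 ng/mL paclitaxel at 6 h, 34 and 220 for 1000 against 1 ng/mL paclitaxel, 96 for glucose in DMSO cells at 24 h and 28 for rapamycin by time.

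The compared groups alone gave 102 for 1 ng/mL rapamycin at 24 h, 1 for 100 against 1 ng/mL rapamycin at 6 h, 38 for 1000 against 1 ng/mL paclitaxel at 6 h, 0 and 0 for glucose in DMSO cells and 0 for paclitaxel by time. Quantile normalization gave 2 for glucose in DMSO cells at 6 h. Array weights gave 91 for glucose in DMSO cells at 24 h, 22 for rapamycin by time, 4 for paclitaxel by time and 1252 for the insulin average at 6 h. Averages over the 7 conditions gave 818 and 461 for insulin and 409 and 1159 for glucose, in place of the DMSO cells. Other alternatives left all counts within a factor of 1.5.

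Of 99 list calls, 76 were lost with an estimated correlation, 44 with fry and 3 with averaged probes. Leaving out run A, B, C or D lost 24, 14, 18 and 14. Camera on 1 difference per run lost 2 and kept 97, among them the ATF4 list of the glucose average at 24 h, whose median lay above 0 in runs A and C, so that test does not show that runs agree. The sterol list in the insulin average at 6 h turned direction without run A (adjusted p = 0.762) and had its lowest adjusted p without run D (0.000637).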

Other observations

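Over all 7 conditions at 24 h, insulin went with higher respiratory chain genes, 9 of 40 members (14 adjusted over the list alone; camera adjusted p = 2.52e-10), led by Cox6c (0.787), Atp5me (0.780) and Cox8a (0.734). The list median was above 0 in each run, at 0.43, 0.08, 0.40 and 0.15 in A to D. Interferon-stimulated genes were higher in 3 of 13 members (4 adjusted over the list alone; adjusted p = 3.28e-05), the transcription factor gene Irf7 (0.932), the immunoproteasome gene Psmb9 (0.741) and B2m (0.490), with run medians of 0.43, 0.23, 0.74 and 0.11. DNA replication genes were higher in 3 of 27 (6 adjusted over the list alone; adjusted p = 0.000312, and adjusted p = 0.363 with an estimated correlation), with a median of 0.63 in run C and at most 0.07 in the others. The p53 targets Ccng1, Phlda3 and Cdkn1a were higher and Gadd45a lower of 16 (adjusted p = 0.00211, and adjusted p = 0.0700 with an estimated correlation), and proteasome genes were higher (4 of 27; adjusted p = 0.00227, and adjusted p = 0.104 with an estimated correlation). Ribosome biogenesis genes (2 of 19; adjusted p = 5.74e-05) and ATF4 targets including Atf4 (2 of 24; adjusted p = 0.00110) were lower, at adjusted p = 0.177 and 0.525 with an estimated correlation. With the runs as the unit limma called 0 probes here.

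The test of rapamycin against insulin was set before its share was computed but after the list results were seen, and that of glucose over time was chosen after the result was seen. Rapamycin may move insulin-responsive genes against insulin: of 188 probes called for insulin in paclitaxel-treated cells at 6 h, 83.0% had the opposite sign under 100 ng/mL rapamycin. Among 100 splits, the real grouping included, 3 gave a share as high, and the highest other was 84.6%. The splits swapped rapamycin and DMSO separately for each set of run, insulin and glucose, so they do not test whether runs agree. The 188 probes were called with arrays as the unit. The interaction of rapamycin with insulin, taken over both hours, called 0 probes by limma, with 509 at an unadjusted p under 0.05. At 6 h the insulin differences under 100 ng/mL rapamycin had a slope of 0.619 on those of the other conditions, the lowest of all conditions. At 24 h their slope was 0.955. A comparison of insulin with and without rapamycin with more independent runs would test this.

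The lower ATF4 targets in 25 mM glucose at 24 h may reflect a rise at 5 mM over time. From 6 to 24 h the list median was 1.51 at 5 mM and -0.0026 at 25 mM, and the chaperone list had 0.787 and 0.174. The ATF4 list had 3.52 and 2.22 in runs B and D, against -0.06 and -0.31 in A and C. The chaperone list at 5 mM had -0.242, 1.34, 0.346 and 1.59 in A to D, so it was above 0 in run C too. These medians used the arrays of the glucose comparisons, so their difference between glucose levels restates those comparisons. What they add is that the ATF4 list moved over time at 5 mM, while its median at 25 mM lay near 0. The sources used here give no measurement of medium glucose, and assaying it at 24 h in each run would test whether it ran low.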
